A study of Mus musculus with 4 samples.

How the data were processed

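Lung immune cells sorted for CD45.2 from 2 wild-type (WT) mice and 2 mice homozygous for the Lmna G609G knock-in (KI), all 15 weeks old, were profiled by 10x Genomics single-cell 3' RNA sequencing (kit version 3.1) with 1 library per mouse. CD45.2 marks leukocytes. Per the labels, about 9600 cells per sample were processed and sequencing aimed at 25000 reads per cell. Per the labels, the authors processed the reads with Cell Ranger 3.0.2 and Seurat 3.0.0 on mm10, while the headers of the count matrices give software version 3.1.0. The deposited table used here holds raw UMI counts of 16689 genes in 18770 cells, which the authors retained from 19819 barcodes called as cells. For genes with unique symbols its values equalled the deposited 10x Genomics matrices except that 875, 838, 1307 and 997 genes in WT mice 1 and 2 and KI mice 1 and 2 are listed at 0. Their 1598, 1567, 2904 and 1811 UMIs lie in at most 2 retained cells per gene and mouse. The filter behind the 1049 barcodes left out is not stated in the labels. The deposited normalised values were not used. The deposited annotation gives each cell a sample name and the name of 1 of 9 clusters.

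Mean expression of marker lists contradicted 7 of the 9 deposited cluster names, so clusters are named here by their markers. The cluster deposited as B cell was led by Retnlg and S100a9 and is called neutrophil-like. That deposited as Neutrophil was led by Ebf1 and Cd79a and is called B-cell-like. That deposited as Naive CD4+ T Cell was led by Apoe and F13a1 and is called monocyte-like. The cluster deposited as Ly6c+ Monocyte was led by Cd8b1 and Cd8a and is called CD8 T-cell-like. The cluster deposited as Naive CD8+ T Cell held Cd4 and Cd3e but also Scgb1a1 and Sftpc among its leading genes, and is called the unnamed Cd4/Cd3e cluster. The cluster deposited as Monocyte Treml4+ was led by Top2a and Elane, with a median of only 654.5 UMIs per cell, and is called the unnamed Elane/Mki67 cluster. Ccl3, Ccl4, Mcpt8 and Cpa3 were among the leading genes of the cluster deposited as CD4+ Treg, called basophil-like here. The names of NK cells and alveolar macrophages matched their markers. Membership of the clusters was taken as deposited, and only the names were changed.

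Raw counts were summed per mouse and cluster and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with robust estimation, TMM normalisation and its filterByExpr filter. P-values were adjusted by Benjamini-Hochberg within each cluster, and genes with an adjusted p below 0.05 were called. The 7 clusters with at least 50 cells in every mouse were tested, and the sum over all cells was tested in the same way. The alveolar-macrophage-like cluster, whose smallest sample held 41 cells, was added after the data had been seen by lowering this limit to 40. Cell numbers per cluster were tested with edgeR against the total number of cells. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, where at least 5 members were measured. Both alternatives rest on the residuals of only 4 mice, so they have little power. Losing a call under them does not by itself argue against a shift, and a call at the preset correlation alone does not establish one. Differences in the genotype effect between clusters were tested with an interaction term and the mouse as a block, for each pair of the 4 largest clusters. These tests, the gene lists and the rule for named genes were set before the data were examined.

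Genes named below were the called genes with a mean of at least 4 on the log2 scale of CPM (counts scaled to the total of each sum after TMM adjustment) and no overlap between the groups. Of these the 10 higher and 10 lower genes with the largest fold were taken in each of the 2 clusters with the most calls, and the 3 higher and 3 lower elsewhere. Up to 4 called members per list, the 10 genes called in the most clusters, and Lmna, Nnt, Xist and Ddx3y were added. Genes outside this rule were chosen after their values were seen, and are named as such. Gene positions come from the GENCODE annotation of GRCm38. Values are given as mean CPM ± SD with n = 2 mice per group, and log2 changes as KI minus WT.

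Retained cells numbered 4770 and 4571 in WT mice 1 and 2, and 4918 and 4511 in KI mice 1 and 2. The corresponding totals were 23077307, 26997500, 21609754 and 22391937 UMIs, and the median UMIs per cell were 3656, 4500, 3642.5 and 3901. Intervals on shares of cells are 95% exact Clopper-Pearson intervals, and the limit for a count of 0 is 3 counts of the total without TMM adjustment. Both cover counting error only.

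The test was tried on a single simulated draw per fit, of the same depth and spread. In it 200 genes, and a further short list of genes, were changed. At a true fold of 2 it recovered from 18% of the changed genes in the unnamed Elane/Mki67 cluster to 86% in the monocyte-like cluster. The share of unchanged genes among the calls was above the nominal level in all fits but the alveolar-macrophage-like one, from 6.86% in the neutrophil-like cluster to 17.6% in the unnamed Cd4/Cd3e cluster and 21.9% in all cells summed. Calls near the threshold therefore hold more false ones than the adjusted p states.

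Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, the replicate number as a block, leaving out each mouse, leaving out called doublets, subtracting the empty-droplet profile (1 to 100 UMIs) at 10% of each sum, and equal cell numbers. Scrublet in scanpy 1.11.5 called 44 doublets at an expected rate of 0.08, so few that leaving out the 8% of barcodes with the highest scores (1411 barcodes) was added after the data had been seen. Blocks of crossed replicate numbers and 20 own Leiden clusters (leidenalg 0.10.2, 2000 variable genes, 30 components, resolution 0.5) were also added then, as was restoring the counts that the table lists at 0. The own clusters matched the deposited ones with an adjusted Rand index of 0.62. Replicate numbers do not pair the mice.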

Results

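The data compare immune cells of the lung between 2 WT mice and 2 KI mice carrying the Lmna G609G allele, which models the premature ageing disorder Hutchinson-Gilford progeria. The question was how this mutation changes gene expression in the immune compartment of the lung. Each mouse gave between 4511 and 4918 retained cells and between 21609754 and 26997500 UMIs. KI mouse 1 stood apart in its cell composition, with 61.7% neutrophil-like cells against 25.6% in KI mouse 2. Its median mitochondrial share over all cells was 0.534% of UMIs per cell, against 3.74% and 3.26% in the WT mice and 4.34% in KI mouse 2. Within clusters it lay close to the others, at 0.290% in neutrophil-like cells (0.317% and 0.421% in WT, 0.356% in KI mouse 2) and 6.23% in B-cell-like cells (5.71% and 6.07% in WT, 6.55% in KI mouse 2).

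Lmna itself (ENSMUSG00000028063, chromosome 3, 88480147 to 88509956, minus strand), which encodes lamins A and C of the nuclear lamina, was not called in any cluster. Over all cells it had 55.8 ± 0.0478 CPM in WT and 43.5 ± 5.06 CPM in KI mice (log2 change -0.36, adjusted p 0.724). It was most abundant in the alveolar-macrophage-like cluster, at 579.7 ± 23.1 and 548.3 ± 25.5 CPM. The codon that G609G names, which reads GGC in the reference, lies at 88482490 to 88482492 in exon 11 of the 12 exons of transcript Lmna-201. The allele itself was not read from these counts. Of the other lamina and envelope genes tested as a list, edgeR called no member in the 7 tested clusters, over all genes or adjusted over the list alone. Nnt, a gene that differs between B6 substrains, was at 2.62 ± 0.308 CPM in WT and 3.15 ± 0.594 CPM in KI mice over all cells. The X-inactivation transcript Xist had 1 and 3 UMIs in the WT mice and 0 and 3 in the KI mice in the 10x matrices, and Y-linked Ddx3y had between 2309 and 2774 UMIs in every mouse.

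Neutrophil-like cells made up 28.01% and 36.6% of the cells of the WT mice, against 61.7% and 25.6% in the KI mice. B-cell-like cells made up 22.3% and 19.4% in WT, and 12.3% and 24.3% in KI mice. Monocyte-like cells made up 16.5% and 17.02% in WT, and 10.4% and 16.8% in KI mice. Alveolar-macrophage-like cells made up 1.61% and 1.95% in WT, and 0.834% and 1.22% in KI mice. None of the 9 shares changed by edgeR (0 at an unadjusted p under 0.05, all adjusted p 0.785), and limma on logit shares also called 0. An exact two-sided permutation test of 2 against 2 mice cannot go below p = 0.333, and the difference between the 2 KI mice was larger than that between the groups in the neutrophil-like cluster. Without KI mouse 2, 2 shares had an unadjusted p under 0.05 and 0 were called.

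**Figure D1:**
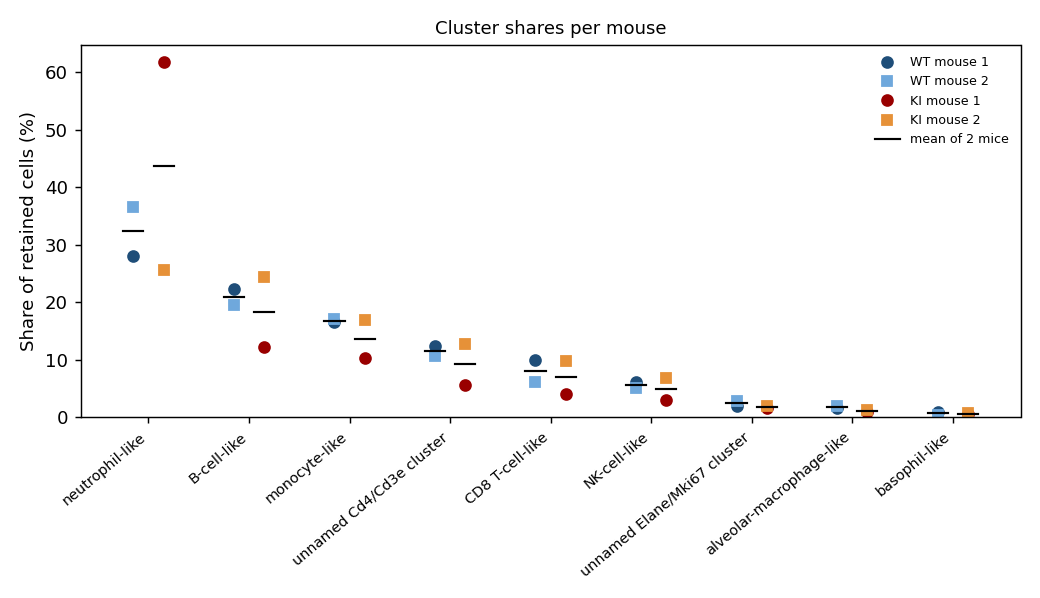
Share of retained cells (%) in each of the 9 clusters, with 1 point per mouse and a line at the mean of the 2 mice of a genotype. KI mouse 1 has 61.7% neutrophil-like cells while the other 3 mice lie between 25.6% and 36.6%.

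In monocyte-like cells Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), a matricellular glycoprotein, rose from 160.0 ± 15.6 to 609.6 ± 21.2 CPM (log2 change 1.93, adjusted p 2.12e-06), and it was also higher in KI empty droplets, at 68.0 and 237.7 CPM. Vcan, a matrix proteoglycan of classical monocytes, rose from 151.6 ± 1.01 to 357.6 ± 33.3 CPM (1.24, adjusted p 1.07e-04). By own clustering this cluster mixed 1691 classical-monocyte-like with 825 non-classical-monocyte-like cells. Those own clusters held 460 and 404 against 250 and 259 cells in the WT mice. In the KI mice they held 355 and 480 against 125 and 206. Neither share of all cells was called (edgeR, unadjusted p 0.930 and 0.310). The mix leaned more to classical-monocyte-like cells in both KI mice, so it may add to increases such as that of Vcan. Cd33 (1.19), the formyl peptide receptor Fpr2 (1.05) and the C-type lectins Clec4d (1.002) and Clec4e (0.90) also rose. The neutrophil transcripts Stfa2l1 (1.81, called) and Retnlg (1.35, not called), looked up after their values were seen, moved with them. The empty-droplet profile, scaled by the neutrophil transcripts S100a8 and S100a9, is called free neutrophil RNA here, although it holds RNA of all sources. It predicted 72.4% and 85.9% of the differences in Stfa2l1 and Retnlg, and 4.86%, 2.68%, 14.9% and 3.26% of those in Cd33, Fpr2, Clec4d and Clec4e. For Thbs1 and Vcan it predicted 0.546% and 0.180% of the differences. With free RNA subtracted Cd33 in monocyte-like cells was not called (adjusted p 0.0542), nor were Fpr2, Clec4d and Clec4e, while Bst1 was. That subtraction took a fixed 10% of each sum. The scaling put free RNA in this cluster at 1.19% (WT) and 1.41% (KI), so the subtraction may take too much. Bst1 (0.91), the coagulation factor F5 (0.87), the cystine transporter Slc7a11 (0.81) and Rbm3 (0.94) completed the 10 largest increases. The complement component C1qb fell by 1.69 on the log2 scale, from 69.0 ± 16.6 to 21.2 ± 5.66 CPM (adjusted p 0.0465), and the efferocytosis receptor Axl fell by 1.52 (adjusted p 0.0176). AA467197 (-2.23), the tetraspanin Cd81 (-1.51), Dapk1 (-1.48), Plxna4os1 (-1.19), Gbp3 (-0.97), Kbtbd11 (-0.96), Pltp (-0.95) and Pla2g16 (-0.93) also fell. An own cluster of cDC2-like cells, 307 of which lay here, numbered 96 and 127 cells in the WT mice. It numbered 37 and 69 in the KI mice, so the mix may also add to decreases. Folr2, a marker of tissue-resident macrophages, had 16 and 54 UMIs in the WT mice and, in the 10x matrices, 0 and 1 in the KI mice, where a count of 0 in KI mouse 1 allows 0.625 CPM.

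Among the lists, 12 of 12 measured genes of MHC class II presentation had a negative log2 change in monocyte-like cells (median -0.52). Of these Ciita, the class II transactivator, was called lower (-0.55), and 4 were lower when adjusted over the list alone. Camera gave an adjusted p of 3.4e-07 at the preset correlation, and the adjusted p was 0.51 with an estimated correlation. This cluster held 307 of 329 cDC2-like cells, an own cluster with H2-Ab1, H2-Eb1 and C1qa among its leading genes, at 2.01% and 2.78% of all cells in the WT mice and 0.752% and 1.53% in the KI mice. In the own cluster of classical-monocyte-like cells, which left them out, 4 of 11 class II genes fell (median -0.52), while Ciita (-0.62, adjusted p 0.0779) and C1qb (-1.25, adjusted p 0.840) were not called. Of 18 genes of the interferon gamma list 2 fell, Gbp3 and Ciita, with 7 adjusted over the list alone (adjusted p 0.617 with an estimated correlation). Of 18 glucocorticoid response genes Tsc22d3 (0.36), Per1 (0.67), Dusp1 (0.50) and Il1r2 (0.75) rose, with 5 higher and 1 lower adjusted over the list alone (adjusted p 0.51 with an estimated correlation). Of 18 genes of the unfolded protein response the chaperones Sdf2l1 (-0.57), Calr (-0.44) and Hsp90b1 (-0.42) fell, with 1 higher and 6 lower adjusted over the list alone, and camera called no shift (adjusted p 0.0675). Of 20 genes of lipid handling Plin2 (0.54) and Apoe (0.39) rose while Nr1h3 (-1.26), Pltp (-0.95) and Fabp4 (-0.82) fell, with 4 higher and 8 lower adjusted over the list alone, and camera called no shift (adjusted p 0.0532). In the classical-monocyte-like own cluster Plin2 and Apoe were called and edgeR called 0 lipid genes lower (8 at an unadjusted p under 0.05), and in the non-classical one it called 0 (6 genes, 3 higher and 3 lower, at an unadjusted p under 0.05). Of 15 neutrophil maturation genes Cxcr4 (0.62) and Il1b (0.48) rose, with 7 adjusted over the list alone (adjusted p 0.51 with an estimated correlation). The epithelial marker Epcam fell by 2.68 beside these groups, the only called gene among 6 epithelial markers, with 4 lower adjusted over the list alone.

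In total 142 of 10533 genes were called in monocyte-like cells, 58 higher and 84 lower, and 1477 had an unadjusted p under 0.05. The groups did not overlap in any of the 142, so leaving out 1 mouse could hardly reverse a direction. A kept direction is therefore no support for these calls. Leaving out WT mouse 1 or 2 gave 1204 and 414 calls, and leaving out KI mouse 1 or 2 gave 8 and 8. All 142 calls kept their direction in these fits, but 4 were called in all of them. Restoring the counts listed at 0 left 140 of the 142.

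In CD8 T-cell-like cells, 7 of 15 genes of cytotoxic effector function fell (adjusted p 0.51 for the list with an estimated correlation). Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), a granzyme of memory cells, went from 50.1 ± 5.64 to 12.3 ± 1.12 CPM (log2 change -1.98, adjusted p 2.26e-06). Klrg1, a receptor of terminally differentiated effectors, fell by 1.49, and the chemokine receptor Cx3cr1 fell by 1.54. Lgals1 (ENSMUSG00000068220, chromosome 15), a galectin of activated T cells, went from 592.6 ± 28.4 to 228.7 ± 0.921 CPM (-1.37, adjusted p 2.77e-10). Ccr7, which guides naive and central memory T cells to lymph nodes, rose from 360.3 ± 47.3 to 571.2 ± 57.9 CPM (0.67, adjusted p 2.28e-04). The quiescence factor Klf2 rose by 0.42 and the costimulatory receptor Icos by 0.96. Further increases among the 10 largest were those of Ifngr2 (1.13), Klhdc1 (1.11), Gm16124 (1.09), Cxcl2 (1.06), Per1 (1.06), Gm14085 (0.99), Sik1 (0.93), Fam241a (0.92) and Tnfaip3 (0.83). Free neutrophil RNA predicted 108% of the difference in Cxcl2. Further decreases were those of the NK receptor genes Klre1 (-1.66) and Klrc2 (-1.47) and of Rap1gap2 (-1.55), Wdr95 (-1.44) and S100a4 (-1.38).

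**Figure D2:**
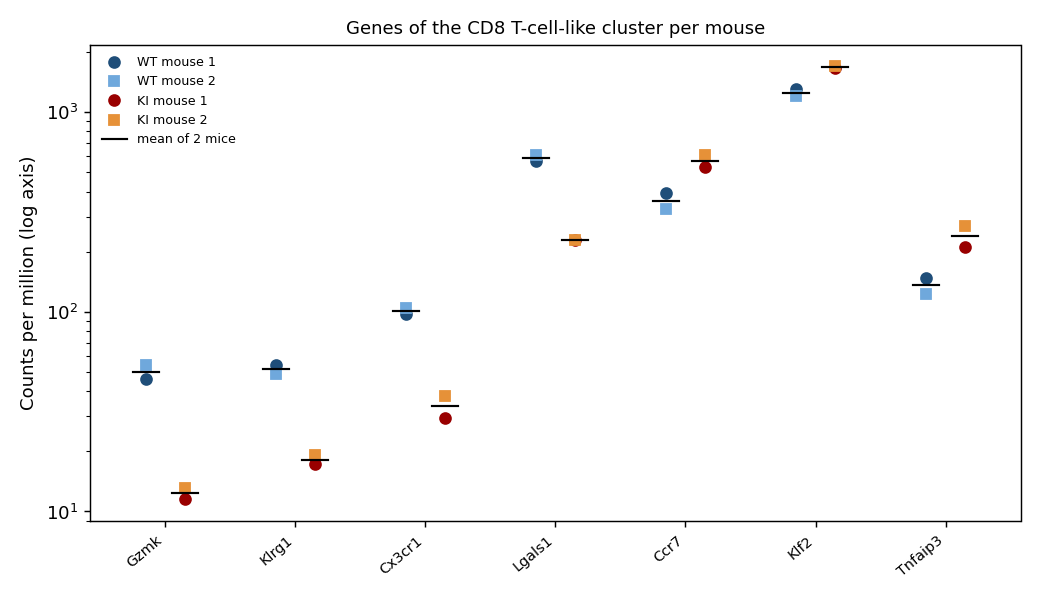
CPM on a log axis of 7 genes in the summed counts of the CD8 T-cell-like cluster, with 1 point per mouse and a line at the mean of the 2 mice of a genotype. Gzmk, Klrg1, Cx3cr1 and Lgals1 lie lower in both KI mice than in both WT mice, and Ccr7, Klf2 and Tnfaip3 lie higher.

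All 15 measured genes of the cytotoxic effector list had a negative log2 change in CD8 T-cell-like cells (median -0.89). Gzmk, Prf1, Nkg7, Klrg1, Cx3cr1, Zeb2 and Id2 were called lower, 13 were lower adjusted over the list alone, and camera gave an adjusted p of 1.6e-35 at the preset correlation. The adjusted p was 0.51 with an estimated correlation. Of 11 naive and central memory genes Ccr7, Klf2 and Satb1 (0.33) rose, with 8 adjusted over the list alone (adjusted p 0.51 with an estimated correlation). An effector subset led by Ccl5 and Gzmk, found by own clustering after the data had been seen, made up 22.6% (18.9 to 26.6%) and 28.2% (22.9 to 33.9%) of the cluster in the WT mice. It made up 9.85% (6.12 to 14.8%) and 12.4% (9.49 to 15.9%) in the KI mice. These intervals cover counting error only, and edgeR across mice did not call its share of all cells (unadjusted p 0.108, adjusted p 0.328). In the own cluster of CD8 T-cell-like cells led by Dapl1 and Lef1, which left that subset out, 110 genes were called, among them Lgals1 (-0.75), S100a4 (-1.34) and Klre1 (-1.75). The cytotoxic effector list had a smaller change there, with a median of -0.25 and 1 of 10 genes called (adjusted p 0.706 with an estimated correlation). Ccr7 was among the leading genes of that own cluster. The smaller effector subset in the KI mice may therefore add to the rise of naive and central memory genes.

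Of 26 nuclear genes of oxidative phosphorylation 7 fell in CD8 T-cell-like cells, among them Atp5k (-0.47) and Cox5b (-0.37), with 10 lower adjusted over the list alone. Of 13 mitochondrially encoded genes 6 rose, among them mt-Nd5 (0.31) and mt-Atp6 (0.24), with 10 higher adjusted over the list alone. Both lists had an adjusted p of 0.51 with an estimated correlation. Of 22 immediate early and heat shock genes Dusp1 (0.69), Zfp36 (0.61), Jund (0.50) and Klf2 rose, with 9 adjusted over the list alone (adjusted p 0.51 with an estimated correlation). Of 18 genes of MHC class I presentation H2-Q7 (-0.90), H2-Q6 (-0.55) and B2m (-0.22) fell, with 1 higher and 6 lower adjusted over the list alone (adjusted p 0.689 with an estimated correlation). Reads of the H2-Q genes are hard to tell apart between paralogs. Of 12 activation and exhaustion genes Icos, Ctla4 (0.78) and Cd69 (0.47) rose while Havcr2 (-2.87) and Tbx21 (-1.23) fell, with 3 higher and 5 lower adjusted over the list alone, and camera called no shift (adjusted p 0.185). In the Dapl1 and Lef1 cluster without the effector subset edgeR called 1 of the 26 oxidative phosphorylation genes lower and 0 of the 13 mitochondrially encoded genes (4 higher at an unadjusted p under 0.05). There it called 7 of 20 immediate early and heat shock genes higher, 1 of 18 MHC class I genes lower, and 2 of 9 activation genes higher and 0 lower (1 lower at an unadjusted p under 0.05).

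In total 229 of 8923 genes were called in CD8 T-cell-like cells, 89 higher and 140 lower, with 1271 at an unadjusted p under 0.05. Here too the groups did not overlap in any call, so a kept direction without 1 mouse is no support. Leaving out WT mouse 1 gave 366 calls, and leaving out KI mouse 1 or 2 gave 87 and 52. All 229 kept their direction in every fit without 1 mouse, and 30 were called in all 4.

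In NK-cell-like cells the cytolytic genes Gzmb (-0.50), Prf1 (-0.46), Klrg1 (-0.71) and Cx3cr1 (-0.90) fell. Prf1, the pore-forming protein of cytotoxic granules, went from 1697 ± 274.3 to 1230 ± 111.7 CPM (adjusted p 0.00668). Endoplasmic reticulum chaperones fell too, with Calr from 386.6 ± 22.3 to 231.3 ± 33.6 CPM (-0.77, adjusted p 2.06e-05), Canx (-0.74), Pdia6 (-0.70) and Hsp90b1 (-0.56). The glucocorticoid response genes Tsc22d3 (0.69) and Txnip (0.65) rose, and so did the NF-kB inhibitor Tnfaip3 (0.999). The largest changes were increases of Clec4e (2.04), Apoe (1.66) and Map2k7 (1.45) and decreases of As3mt (-1.20), Il27ra (-1.05) and Fkbp2 (-0.93). Free neutrophil RNA predicted 15.9% of the difference in Clec4e.

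Of 14 cytotoxic effector genes 6 fell in NK-cell-like cells, Gzma and Nkg7 included, with 1 higher and 6 lower adjusted over the list alone. The camera adjusted p of 6.2e-06 became an adjusted p of 0.573 with an estimated correlation. Of 16 genes of the unfolded protein response 4 fell, with 7 adjusted over the list alone, and the adjusted p of 9.1e-08 became an adjusted p of 0.51 with an estimated correlation. Of 12 glucocorticoid response genes 2 rose, with 5 adjusted over the list alone (adjusted p 0.51 with an estimated correlation). In total 75 of 7793 genes were called, 33 higher and 42 lower, with 731 at an unadjusted p under 0.05. Without WT mouse 1 there were 126 calls and without KI mouse 1 there were 34, and 15 genes were called in all 4 such fits.

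In neutrophil-like cells Ccl4, a chemokine of inflammation, rose from 113.9 ± 9.93 to 262.2 ± 7.39 CPM (log2 change 1.203, adjusted p 0.0318). Rdh11 (1.51), the protease inhibitor Stfa1 (1.48) and Cyth1 (1.24) also rose. Scgb1a1, a secretory protein of airway club cells and not of neutrophils, fell by 3.66, from 312.0 ± 102.2 to 24.3 ± 3.60 CPM (adjusted p 0.00439), and in empty droplets it changed by -4.50. All 28 measured genes of the type I interferon list had a negative log2 change (median -0.97). Camera gave the list an adjusted p of 2.3e-21 at the preset correlation, and the adjusted p was 0.573 with an estimated correlation. None of them was called by edgeR, while 8 were lower adjusted over the list alone. Without WT mouse 2 the median was -0.29. A subset led by interferon genes, found by own clustering after the data had been seen, made up 7.93% (6.54 to 9.52%) and 18.8% (16.98 to 20.8%) of neutrophil-like cells in the WT mice, and 3.63% (2.99 to 4.35%) and 4.16% (3.08 to 5.47%) in the KI mice. Its share of all cells was not called by edgeR across mice (unadjusted p 0.0739, adjusted p 0.328).

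In monocyte-like cells 28 of 30 genes of the type I interferon list were negative (median -0.22), with 0 called by edgeR and 0 adjusted over the list alone (adjusted p 0.717 with an estimated correlation). The 5 genes of 8332 called in neutrophil-like cells, with 627 at an unadjusted p under 0.05, were called in all 4 fits without 1 mouse. Those fits gave 156 and 15 calls without WT mouse 1 or 2, and 128 and 113 without KI mouse 1 or 2, and DESeq2 gave 34. With free RNA subtracted edgeR called 0 (581 at an unadjusted p under 0.05), and with equal cell numbers or the replicate block it called 1 each.

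In B-cell-like cells Tnfaip3, a feedback inhibitor of NF-kB, rose from 27.2 ± 8.24 to 57.6 ± 1.91 CPM (log2 change 1.10, adjusted p 0.0275). Hs3st1 (1.04), Rab30 (1.03), Plaur (1.02), Cebpb (1.02) and Klf6 (0.85) rose as well. Id3, an inhibitor of E-protein transcription factors, fell by 1.31, and the light chain gene Iglc1 went from 704.8 ± 59.4 to 453.1 ± 5.48 CPM (-0.64). Of 16 p53 targets Gadd45a (0.89) and Sesn1 (0.60) rose, with 4 higher and 2 lower adjusted over the list alone, and camera called no shift (adjusted p 0.106). The median of that list was -0.03 while its mean and its test pointed up.

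Of 18 NF-kB and cytokine genes 1 rose in B-cell-like cells, with 7 adjusted over the list alone and a median of 0.56. Free neutrophil RNA predicted 111% and 92.8% of the differences in the members Cxcl2 and Il1b, and was not computed for the others. The adjusted p of 1.6e-09 became an adjusted p of 0.51 with an estimated correlation. In total 22 of 9565 genes were called, 20 higher and 2 lower, with 1181 at an unadjusted p under 0.05. Without WT mouse 1 or 2 there were 843 and 137 calls, without KI mouse 1 there were 123, and 10 genes were called in all 4 fits without 1 mouse.

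In the unnamed Cd4/Cd3e cluster the chemokine Cxcl2 rose from 30.2 ± 3.06 to 125.3 ± 18.7 CPM (log2 change 2.03, adjusted p 1.09e-05), a difference of which free neutrophil RNA predicted 57.6%. The T-cell inhibitory receptor Ctla4 rose from 116.8 ± 3.43 to 203.4 ± 17.1 CPM (0.80, adjusted p 0.00342), and Txnip rose by 0.70. Genes of non-immune cells also moved in this cluster. The matrix gene Mgp rose from 3.47 ± 2.53 to 60.4 ± 17.5 CPM, with Tmem100 (5.17) and Tns1 (3.11). All 22 cells of an own cluster that was endothelial-like, with Mgp among its leading genes, lay in this cluster, 3 and 3 in the WT mice and 9 and 7 in the KI mice. Tppp3 (-2.09) and Il17re (-2.02) fell. All 54 cells of a gamma-delta T-cell-like own cluster, with Trdc and Il17a among its leading genes, lay here too. They numbered 12 and 28 in the WT mice and 5 and 9 in the KI mice, so the mix may add to decreases. Their share of all cells was not called (edgeR, unadjusted p 0.0743). The surfactant gene Sftpd had 129 and 205 UMIs in the WT mice and is listed at 0 in both KI mice (adjusted p 2.06e-04), for which the 10x matrices hold 19 and 9 UMIs in 1 cell each. With such counts restored its change was -3.21 and was not called (adjusted p 0.342).

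Of 9 endothelial markers Tmem100, Cav1 (2.86) and Egfl7 (1.90) rose in this Cd4/Cd3e cluster, with 7 adjusted over the list alone. Of 5 fibroblast markers Mgp and Bgn (5.22) rose, with 3 adjusted over the list alone. Of 10 epithelial markers Sftpd fell, with 2 adjusted over the list alone. With the counts listed at 0 restored Tmem100 (5.18, adjusted p 0.0523) and Bgn (2.71, adjusted p 0.0926) were not called either. Of 16 glucocorticoid response genes Cebpd (1.72) and Txnip rose, with 7 adjusted over the list alone. Of 13 neutrophil maturation genes Retnlg (1.02) and Il1b (0.71) rose, with 6 adjusted over the list alone, and free neutrophil RNA predicted 137% and 105% of their differences. Each of these 5 lists had an adjusted p of 0.51 with an estimated correlation. In total 62 of 9423 genes were called, 52 higher and 10 lower, with 827 at an unadjusted p under 0.05. Without WT mouse 1 or 2 there were 382 and 266 calls, without KI mouse 1 or 2 there were 7 and 35, and without the barcodes with the highest doublet scores there were 4. Restoring the counts listed at 0 gave 51 calls, 49 of them among the 62.

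In the unnamed Elane/Mki67 cluster Tcf7, a transcription factor of lymphoid progenitors and T cells, rose from 62.5 ± 9.61 to 280.4 ± 18.8 CPM (log2 change 2.15, adjusted p 0.0231). Plbd1, a phospholipase of myeloid cells, went from 156.3 ± 7.43 to 6.13 ± 3.20 CPM (-4.78, adjusted p 0.00809). Of the UMIs of this cluster 83.8% and 82.7% in the WT mice and 52.9% and 79.9% in the KI mice lay in 29, 26, 5 and 15 cells of an own cluster of mixed lymphoid and epithelial markers. Tcf7 and Plbd1 were the 2 calls among 5535 genes, with 391 at an unadjusted p under 0.05. They were called in all 4 fits without 1 mouse, which gave 64 and 114 calls without WT mouse 1 or 2, and 126 and 25 without KI mouse 1 or 2. Without the highest doublet scores edgeR called 0 (81 at an unadjusted p under 0.05), and in the own cluster led by Elane and Prtn3 it called 1 other gene.

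Summed over all cells, edgeR called 0 of 13293 genes, with 906 at an unadjusted p under 0.05, and DESeq2 called 55. Tppp3, a tubulin polymerisation protein, was at 108.9 ± 4.04 and 56.9 ± 0.408 CPM (log2 change -0.94, adjusted p 0.362). Plaur, the urokinase receptor, was at 163.5 ± 10.2 and 345.2 ± 59.6 CPM (1.08, adjusted p 0.542). These sums mix cell shares with expression, and without KI mouse 2 edgeR called 1264 genes, against 35, 18 and 5 without WT mouse 1, WT mouse 2 or KI mouse 1.

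Rbm3 (ENSMUSG00000031167, chromosome X, 8138975 to 8145880), an RNA-binding protein induced by mild cold, had a positive log2 change in all 8 clusters. It was called in 6 of them, the B-cell-like (0.75), monocyte-like (0.94), Cd4/Cd3e (0.76), CD8 T-cell-like (0.56), NK-cell-like (0.80) and alveolar-macrophage-like (1.09) ones. In NK-cell-like cells it rose from 358.8 ± 23.7 to 622.8 ± 51.2 CPM (adjusted p 5.42e-07). In empty droplets Rbm3 was at 321.4 ± 12.98 and 492.6 ± 37.4 CPM (0.62, adjusted p 0.576). The salt-inducible kinase Sik1 was called higher in 5 clusters, and Tnfaip3 and the RNA-decay factor Zfp36l2 in 4. H2-Q7 was called lower in 3, the CD8 T-cell-like (-0.90), Cd4/Cd3e (-0.61) and NK-cell-like (-0.60) clusters.

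**Figure D3:**
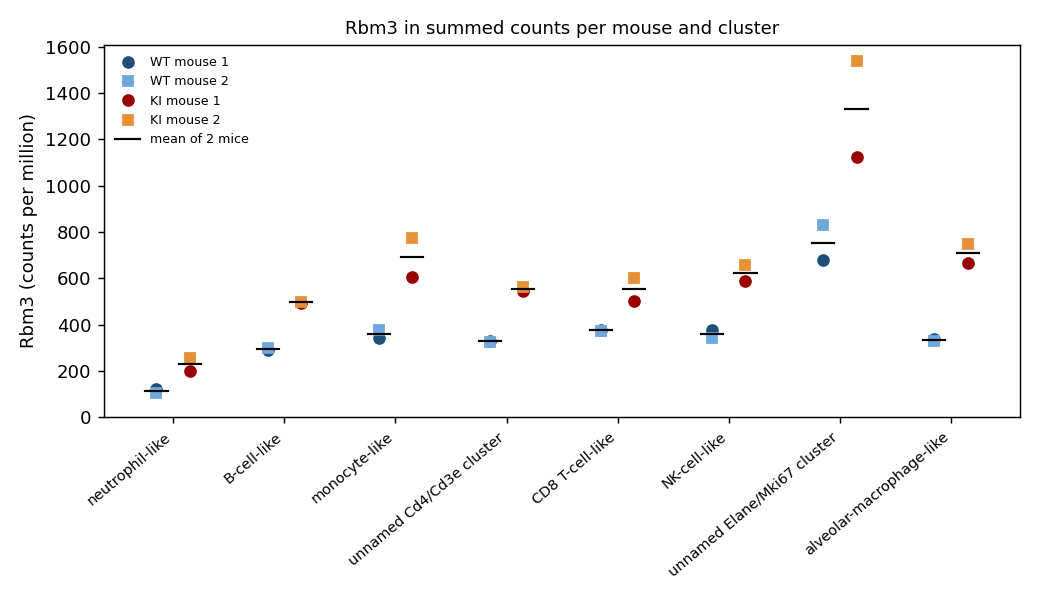
CPM of Rbm3 in the summed counts of each of 8 clusters, with 1 point per mouse and a line at the mean of the 2 mice of a genotype. Both KI mice lie above both WT mice in every cluster shown.

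Over the 7 tested clusters and all cells, camera called 91 of 226 pairs of list and cluster at the preset correlation. With an estimated correlation 0 held (smallest adjusted p 0.51), and fry called 0. With so few mice these alternatives had little power, so they do not decide whether a list shifted. In every call reported the groups did not overlap, which holds for 0.333 of genes by chance and held for 36.9% to 45.2% of the genes tested per cluster.

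The genotype effect differed between clusters for named genes. Cd33, Clec4e, Bst1 and Fpr2 rose more in monocyte-like than in neutrophil-like cells, by 0.88, 0.83, 0.86 and 0.81 on the log2 scale. The neutrophil transcripts Retnlg (1.06), Stfa2l1 (1.26), S100a9 (0.84) and S100a8 (0.78), looked up after their values were seen, differed in the same direction. In empty droplets the log2 changes of Cd33, Clec4e, Bst1 and Fpr2 were 1.10, 0.83, 0.70 and 0.79, none of them called (adjusted p 0.593 to 0.671), and free neutrophil RNA predicted 1.64% to 4.86% of their differences in monocyte-like cells. Cd81 differed by -1.53 between monocyte-like and B-cell-like cells. The mix of cells within the monocyte-like cluster also differed between the groups, so such differences are not shown to arise within monocytes. Interaction tests called 71 genes between neutrophil-like and monocyte-like cells, 30 between monocyte-like cells and the Cd4/Cd3e cluster, 21 between neutrophil-like cells and the Cd4/Cd3e cluster, 19 between B-cell-like and monocyte-like cells, and 10 between neutrophil-like and B-cell-like cells. Between B-cell-like cells and the Cd4/Cd3e cluster edgeR called 0, with 553 at an unadjusted p under 0.05, and no other tool was run. These were 130 distinct genes, against 862 without WT mouse 1 and 259 without WT mouse 2.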

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

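The tests of free RNA and of the interferon pattern below were chosen after the results were seen, while the test of a lower temperature was set before the data for it were examined.

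Interaction tests called differences in the genotype effect for 10 genes between neutrophil-like and B-cell-like cells, 71 between neutrophil-like and monocyte-like cells, 21 between neutrophil-like cells and the Cd4/Cd3e cluster, 19 between B-cell-like and monocyte-like cells, and 30 between monocyte-like cells and the Cd4/Cd3e cluster. The values that follow are differences between 2 clusters in the log2 change. Against neutrophil-like cells, monocyte-like cells differed by -1.99 for AA467197, -1.46 for Cd81, -1.15 for Rdh11, -0.72 for Cyth1, 0.88 for Cd33, 0.83 for Clec4e, 0.86 for Bst1 and 0.81 for Fpr2. The neutrophil transcripts Retnlg (1.06) and Stfa2l1 (1.26) differed in the same direction between these clusters. Against B-cell-like cells, monocyte-like cells differed by -1.53 for Cd81, -0.97 for Gbp3 and -0.88 for Tnfaip3. Against monocyte-like cells, the Cd4/Cd3e cluster differed by 3.83 for Tns1, 2.32 for Cd81, 1.88 for Gbp3, 5.49 for Mgp and -1.50 for Tppp3. Against neutrophil-like cells, it differed by 3.48 for Tns1 and -1.30 for Cyth1, and B-cell-like cells differed by -1.12 for Cyth1. The Cd4/Cd3e cluster held 22 endothelial-like cells with Mgp among their leading genes, 3 and 3 in the WT mice and 9 and 7 in the KI mice. Most cDC2-like cells, 96 and 127 in the WT mice and 37 and 69 in the KI mice, lay in the monocyte-like cluster. Its differences therefore may reflect its mix of cells.

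In empty droplets, which the comparisons do not use, 1 gene was higher in KI mice. This was Thbs1, at 68.0 ± 8.37 CPM in WT and 237.7 ± 20.4 CPM in KI mice (log2 change 1.81, adjusted p 0.0158, n = 2 per group). Another 15 of 10512 genes were lower, Scgb1a1 among them (-4.50).

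Rbm3 was higher in KI mice in every tested cluster, and a candidate source is free RNA, which would cap the difference at that of empty droplets, 149 CPM on totals without TMM adjustment. On the same scale the median difference over the 7 tested clusters was 228 CPM, which argues against free RNA as the whole source. Neutrophil-like cells (116 CPM) lay below the cap and CD8 T-cell-like cells (165 CPM) close to it. That cap holds for sums made of free RNA alone. Scaled by S100a8 and S100a9, free RNA made up 1.09% (WT) and 1.13% (KI) of CD8 T-cell-like sums. In monocyte-like cells it predicted 0.951% of the Rbm3 difference. These values argue against free RNA as the source in CD8 T-cell-like and monocyte-like cells, while neutrophil-like cells cannot be scaled this way. A response to a lower temperature would also lower chaperones driven by heat shock factor, and their median was below 0 in 6 of the 7 clusters, which met the bound set beforehand. That bound was judged too weak after the result was seen, because medians such as -0.011 in neutrophil-like and -0.0038 in CD8 T-cell-like cells lay near 0 with members going both ways. Among the 7, camera gave an unadjusted p under 0.05 in only monocyte-like (0.0347) and NK-cell-like cells (6.68e-06). In these edgeR called 1 and 0 chaperones lower. A lower temperature therefore cannot be told apart from other effects. In alveolar-macrophage-like cells, outside the 7, all 9 chaperones had a negative log2 change and edgeR called 0 of them (median -0.34, unadjusted camera p 1.74e-05). Cirbp, a related cold-induced gene looked up after its values were seen, was higher in all 8 clusters, with log2 changes from 0.46 to 1.14 and calls in 2. An effect of the Lmna genotype stays open and untested.

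Type I interferon genes had a median log2 change of -0.97 in neutrophil-like cells, where edgeR called 0 of them over all genes and 8 lower adjusted over the list alone, and the list's camera call was lost with an estimated correlation (adjusted p 0.573). Own clustering split these cells, and the subset led by interferon genes made up 7.93% and 18.8% of them in the WT mice against 3.63% and 4.16% in the KI mice. Outside that subset the list median was still -0.41 and -0.81 in the 2 other tested subsets. Camera adjusted p there was 2.3e-09 and 2.9e-19, and became an adjusted p of 0.706 with an estimated correlation. The subsets were cut from the same expression values and were not refitted without WT mouse 2. These medians therefore do not settle whether a smaller share of interferon-high neutrophils was the source. A single WT mouse with a high interferon level cannot be told apart from a genotype effect, because the median without WT mouse 2 was -0.29, between the bounds set for the test. An effect of the Lmna genotype stays open and untested.

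Transcripts abundant in neutrophils and monocytes, such as Cxcl2, Cebpb, Plaur and Clec4e, were called higher in lymphoid clusters of KI mice. The empty-droplet profile, scaled by S100a8 and S100a9 as a measure of free neutrophil RNA, predicted a median of 33.1% of the difference over 11 such calls. Predictions ran from 5.57% for Plaur in B-cell-like cells to 137% for Retnlg in the Cd4/Cd3e cluster. This lies between the bounds set for the test, so free RNA and expression in the lymphoid cells cannot be told apart for the set. An effect of the Lmna genotype on lymphoid cells stays open and untested.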

How the results depend on the processing

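Alternatives added after the data were seen were the crossed replicate numbers, the highest doublet scores, the own clusters, the restored counts and the alveolar-macrophage-like cluster. Testing shares outside the neutrophil-like cluster was also added then, and edgeR called 0 of them (all adjusted p 0.965). The other alternatives were set beforehand. Over 268 pairs of named gene and cluster, 3848 alternative values gave 3130 with the same direction and side of the threshold, 622 weaker, 95 stronger and 1 reversed. The reversed one was Ighm in monocyte-like cells, -0.44 in the main fit and 0.040 with free RNA subtracted (adjusted p 0.990), where Ighm is a B-cell transcript and the subtraction takes it from every sum. On simulated data of this depth the test recovered between 0% and 54% of genes changed by a fold of 1.5, so changes of that size can be missed.

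Leaving out 1 mouse at a time gave 15 to 156 calls in neutrophil-like, 22 to 843 in B-cell-like, 8 to 1204 in monocyte-like, 7 to 382 in Cd4/Cd3e, 52 to 366 in CD8 T-cell-like, 34 to 126 in NK-cell-like, 25 to 126 in Elane/Mki67 and 12 to 107 in alveolar-macrophage-like cells. The range was 5 to 1264 for all cells, 82 to 98 for lists, 148 to 862 for interactions and 0 to 0 for shares. The group left with 1 mouse is assumed to vary like the other. Without the low-count filter there were 196 calls in neutrophil-like, 324 in B-cell-like, 735 in monocyte-like, 154 in Cd4/Cd3e, 366 in CD8 T-cell-like and 107 in Elane/Mki67 cells, and 445 interactions. With replicate numbers as a block there were 1 in neutrophil-like, 451 in monocyte-like, 147 in CD8 T-cell-like and 104 in Elane/Mki67 cells. With crossed numbers as a block there were 294 in neutrophil-like, 182 in B-cell-like, 384 in monocyte-like, 354 in CD8 T-cell-like and 159 in alveolar-macrophage-like cells, and 24 in all cells. With free RNA subtracted there were 0 in neutrophil-like (edgeR, 581 at an unadjusted p under 0.05), 14 in B-cell-like, 63 in monocyte-like and 5 in Elane/Mki67 cells. With equal cell numbers there were 1 in neutrophil-like, 80 in B-cell-like, 9 in Cd4/Cd3e, 22 in NK-cell-like, 20 in Elane/Mki67 and 32 in alveolar-macrophage-like cells. Without the highest doublet scores there were 47 in B-cell-like, 74 in monocyte-like, 4 in Cd4/Cd3e, 0 in Elane/Mki67 (edgeR, 81 at an unadjusted p under 0.05) and 48 in alveolar-macrophage-like cells. DESeq2 gave 34 in neutrophil-like, 48 in B-cell-like, 34 in Cd4/Cd3e, 102 in CD8 T-cell-like, 26 in NK-cell-like and 17 in alveolar-macrophage-like cells, and 55 in all cells. The matched own clusters gave 18 in neutrophil-like, 52 in monocyte-like, 110 in CD8 T-cell-like and 1 in Elane/Mki67 cells. Another neutrophil-like own cluster, led by Gm5483 and Retnlg, gave 7, and the non-classical-monocyte-like one gave 17. For lists an estimated correlation gave 0 and fry 0, against 91 by camera. The cause of these differences was not tested.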

Other observations

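The alveolar-macrophage-like cluster and the own clusters were tested after the data had been seen, and the test of genes near Lmna was set before its result was seen.

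In alveolar-macrophage-like cells Rbm3 rose from 334.0 ± 6.23 to 708.4 ± 58.9 CPM (log2 change 1.09, adjusted p 2.88e-08, n = 2 mice per group). Chil3, a chitinase-like protein abundant in these cells, rose from 11451 ± 535.5 to 16186 ± 103.8 CPM (0.50, adjusted p 8.05e-04). Lmnb1, which encodes lamin B1 of the nuclear lamina, rose from 25.6 ± 3.60 to 57.2 ± 10.1 CPM (1.14, adjusted p 0.0186), and the cell cycle inhibitor Cdkn1a rose by 0.57. In empty droplets Lmnb1 was at 258.7 and 522.9 CPM (1.01, adjusted p 0.562), and free neutrophil RNA, scaled by S100a8 and S100a9, predicted 12.4% of its difference in this cluster. Lmnb1 in alveolar-macrophage-like cells was not called without WT mouse 1, KI mouse 1 or KI mouse 2 (adjusted p 0.121, 0.314 and 0.174). Cldn1 (1.71), the costimulatory ligand Cd86 (1.57) and Ier3 (1.47) had the largest increases, and Id3 (-3.09), the club cell gene Scgb1a1 (-2.28) and the chemokine Cxcl1 (-2.00) the largest decreases. The matrix protein Spp1 fell by 1.17. Of 24 NF-kB and cytokine genes Ier3, Tnfaip3 (0.86), Cxcl2 (0.54) and Nfkbia rose and Cxcl1 fell, with 12 higher and 1 lower adjusted over the list alone. The adjusted p of 2.6e-07 became an adjusted p of 0.927 with an estimated correlation. In total 76 of 7903 genes were called, 46 higher and 30 lower, with 754 at an unadjusted p under 0.05 and 12 calls without KI mouse 2.

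Own clustering separated classical-monocyte-like cells from cDC2-like cells, which made up 2.01% and 2.78% of the cells of the WT mice and 0.752% and 1.53% of those of the KI mice, a share that was not called (unadjusted p 0.115). In the classical-monocyte-like cells 52 genes were called, 27 higher and 25 lower. Thbs1 (1.73), Vcan (0.96), Cd33 (1.22) and Clec4e (0.91) rose there, and Axl (-1.66) fell. Of 11 genes of MHC class II presentation 4 fell, Cd74 (-0.59) and H2-Ab1 (-0.63) among them, with an adjusted p of 0.706 with an estimated correlation.

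Genes near Lmna may differ between the groups because DNA around the knock-in allele was inherited with it. Within 20 Mb of Lmna 12 of 277 tested genes were called in a cluster, or 4.33%, against 3.77% elsewhere. The odds ratio was 1.15 (95% interval 0.584 to 2.07, two-sided Fisher's exact test, p 0.631), between the bounds set for the test, so linked DNA cannot be told apart from other sources of change for these 12 genes. They were Etv3, Krtcap2, S100a13, S100a4, S100a6, S100a11, S100a10, Ecm1, Txnip, Rhoc, Fcrls and Syt6. This limit therefore covers the changes of S100a4 and Txnip given above. Chil3 (chromosome 3, 106147554 to 106167564), called in alveolar-macrophage-like cells outside this test, lies in the same window.

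The barcodes left out of the deposited table numbered 199 and 350 in the WT mice and 325 and 175 in the KI mice. Their median UMIs were 9387 and 8959 in WT and 7010 and 9548 in KI mice. Those of the retained cells were 3656 and 4500 in WT and 3642.5 and 3901 in KI mice. A marker counted as present with any UMI, so the shares below are not comparable between barcodes left out and retained. At least 50% of the neutrophil markers were present in 51.3% and 84.0% of them in WT, and in 91.4% and 45.1% in KI mice, against 27.2% and 36.5% of the retained cells in WT and 60.5% and 25.5% in KI mice. For B-cell markers the shares were 37.7% and 16.9% of those left out in WT and 9.85% and 51.4% in KI mice, against 21.3% and 17.9% of the retained cells in WT and 11.4% and 22.4% in KI mice.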
